A study of Mus musculus with 15 samples.

How the data were processed

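RNA from sorted mouse HSCs was amplified with a low-input full-length cDNA kit (SMART-Seq v4) and made into libraries by tagmentation (Nextera XT), per the labels' protocols. The 15 libraries form 5 groups of 3. The submitters' processing notes list kallisto 0.43.0, which assigns reads to transcripts without aligning them to the genome, and the build GRCm38. How transcripts were combined into genes, the unit before normalization and the offset before the logarithm are not given in the sources used here. The authors deposited one table of log2 values, 1 row per gene symbol and 1 column per library. From the values themselves, the columns are quantile normalized: they share one distribution apart from ties at the lowest values, and the lowest value of the file is 0.1375, the log2 of 1.1 (0.1409 in GFP2 replicate I and 0.1907 in Total replicate II). Quantile normalization removes differences in total RNA and in the shape of the distribution. It also means that a gene which enters the top ranks of a library pushes the genes below it to lower values. Read depth is unknown, so no counting intervals or floors are given. In the symbol column 26 gene names had been turned into dates and were left as deposited. Of 31298 symbols, 30184 matched the reference gene table; coordinates of named genes come from the GENCODE annotation of GRCm38.

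The design fixed before the data were examined named a count test for counts and limma on log2 values for normalized units. The file held log2 values, so they entered limma as deposited with no further pseudocount. Linear values, 2 to the power of the deposited value minus 1, were used for filters and shares. Genes with a linear value of at least 1 in at least 3 libraries were tested (27994 genes). One mean per group was fitted to all 15 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend and robust empirical Bayes moderation (residual df 10) and no covariate, and p-values were adjusted by Benjamini-Hochberg within each comparison at 0.05. Comparisons were GFP1 against GFP4, the linear trend over the 4 bins, the 3 pairs of neighbouring bins and each bin against Total. Differences are log2 values, first group minus second, with limma's moderated standard error. They understate changes of genes near the lowest value.

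Gene lists fixed before the data were examined numbered 30: HSC signature, megakaryocyte and platelet, erythroid, granulocyte-monocyte, lymphoid, S phase, G2 and M phase, G1 entry and quiescence, PRC2, PRC1, DNA methylation, H3K27 demethylases and trithorax, immediate early, interferon response, oxidative phosphorylation, glycolysis, ribosome biogenesis, cholesterol synthesis, p53 targets, age-associated HSC genes, sort gate markers, neutrophil, macrophage, B cell, T and NK cell, mast cell and basophil, endothelial and stromal, multipotent progenitor, ribosomal protein and mitochondrially encoded genes. They were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry, adjusted over the 30 lists. After immunoglobulin transcripts had been seen, 5 lists were added: plasma cell, early erythroid and megakaryocyte regulators, late erythroid, late megakaryocyte and platelet, and immunoglobulin genes.

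The rule for named genes was fixed before the data were examined. For GFP1 against GFP4 it took the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 10 ppm of the summed linear values over the 15 libraries, all 3 libraries of one bin above all 3 of the other, and a symbol that is not a predicted gene. The trend took 5 each way by smallest p, the other comparisons 3 each way by size, and each list up to 2 each way by smallest p; 20 genes were named in every case. The 10 leading genes outside the immunoglobulin genes were added after their values were seen.

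The model was tested on simulated data with Gaussian noise of the fitted spread. For GFP1 against GFP4, with 200 of 27994 genes changed, it recovered 28% of the genes changed by 1 on the log2 scale and 51% of those changed by 2, called 4 unchanged genes and made 0 sign errors. Genes were drawn at all expression levels, so the recovered share includes genes near the lowest value. The measured libraries had 19.5% of genes called, a far larger share than was changed in the simulation, and the adjusted threshold depends on that share. Simulated genes were also independent, with no lowest value and no quantile normalization. The recovered percentages are therefore not the sensitivity of the measured comparison. Alternatives fixed beforehand were quantile normalization repeated over all genes, no filter, array weights, replicate number as a block, a fit of the compared groups alone, a pseudocount of 0.1, bin number as a numeric covariate and each library left out in turn. Those added after seeing the data were a filter at a mean of 1 ppm, median-of-ratios rescaling, the number of genes at the lowest value as a covariate, quantile normalization without immunoglobulin genes and Jchain, and fits to the GFP4, GFP3 and GFP2 libraries alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.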

Results

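Gene expression was measured by RNA sequencing in hematopoietic stem cells (HSCs) of mouse bone marrow, divided by how much of a histone label they had kept. The mice carried a tetracycline-regulated histone H2B fused to green fluorescent protein (GFP) under a transactivator driven by human CD34 regulatory sequence. Doxycycline switches the label off, so that each cell division dilutes it. HSCs were sorted as lineage-negative, Sca1-positive, c-Kit-positive cells that were CD48-negative, Flk2-negative and CD150-positive, and were then divided into 4 bins, GFP4, GFP3, GFP2 and GFP1. The undivided HSC sort is called Total. Each of the 5 groups had 3 libraries, 15 in all, numbered I, II and III. In every group these came from mice aged 5, 5.5 and 6.5 months after 12, 14 and 16 weeks of doxycycline, respectively. The labels do not state which end of the numbering holds the most label; the number is read here as rising with label, and every comparison is given by bin name. The replicates of a group differ in age and length of doxycycline and so came from different mice. The labels do not say whether each was 1 mouse or a pool, or whether the groups of one number share mice, so the p-values measure the spread between these libraries.

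The values were log2 expression per gene symbol for 31298 symbols, of which 27994 were tested. The 15 libraries share one distribution apart from ties at its lowest values, so read depth is unknown and any difference in total RNA between bins is removed. Among 10337 genes with a mean of at least 10 ppm of the summed linear values, libraries of one group correlated with Pearson's r between 0.857 and 0.977 (median 0.963, 15 pairs). Pairs from different groups had r between 0.669 and 0.978, with a median of 0.825. These correlations are across genes, which are not independent replicates. The first principal component held 65.6% of the variance. The GFP1 and Total libraries lay on one side of it, from 35.5 to 70.5. All GFP2, GFP3 and GFP4 libraries lay on the other, from −54.1 to −23.8. Immunoglobulin genes, described next, were among the genes used for the correlations and the component. Neither was repeated without them, so their part in this split was not tested.

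Immunoglobulin transcripts set the GFP1 and Total libraries apart from the rest. Immunoglobulin genes took 4.92% to 5.28% of the summed linear values in the 3 GFP1 libraries and 4.34% to 5.49% in the 3 Total libraries. They took 0.00726% to 0.0737% in the 9 libraries of GFP2, GFP3 and GFP4. All libraries share one distribution, in which the top 10 genes take 6.433% in every group. These shares therefore follow the ranks of the genes and are not shares of RNA. Igkc, the kappa light chain constant gene, was the most abundant gene in all 6 GFP1 and Total libraries, where its value (19.12) is the highest the common distribution allows. Its mean was 11.47 ± 1.81 in GFP4 and 9.60 ± 0.52 in GFP2 (SD, n = 3). Of 338 variable segments in the file, 116 to 133 exceeded a log2 value of 8 in GFP1 and 60 to 83 in Total, against 0 to 3 elsewhere. Variable segments resemble each other closely, so the value of any single segment is uncertain.

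**Figure D1:**
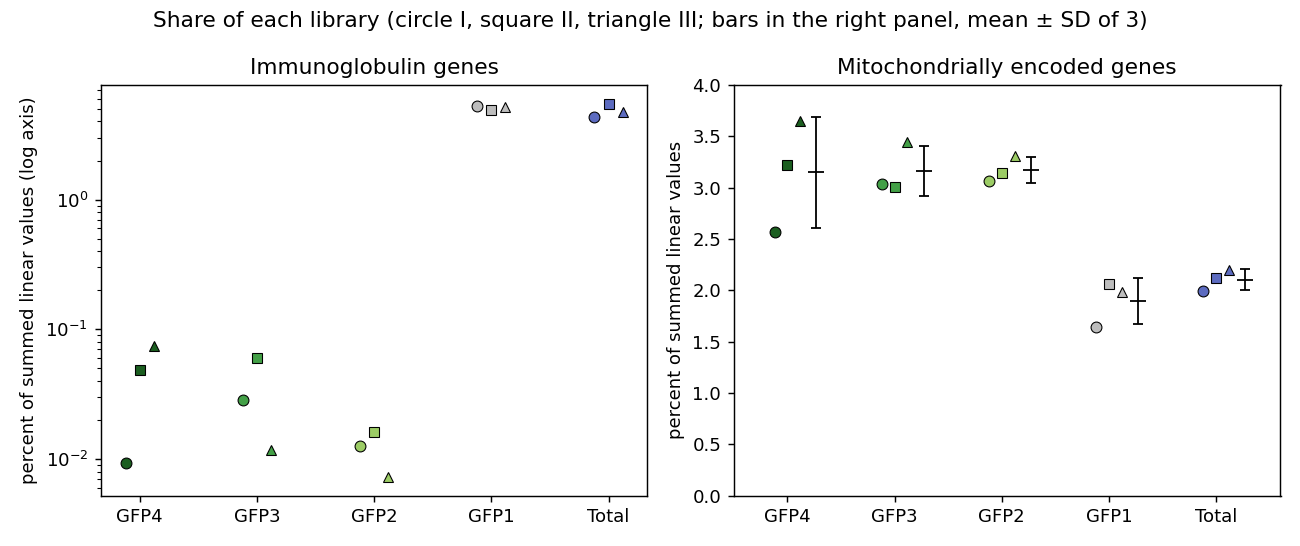
Percent of each library's summed linear values in immunoglobulin genes (left, log axis) and in mitochondrially encoded genes (right) for the 3 libraries of each group; bars at right are mean ± SD. The immunoglobulin share lies between 4.34% and 5.49% in GFP1 and Total and at or below 0.0737% in the other bins, and the mitochondrial share is 1.65% to 2.20% against 2.57% to 3.65%.

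GFP1 was compared with GFP4 to ask how HSCs at the ends of the label range differ. Genes of the HSC signature were lower in GFP1 and genes of the cell cycle were higher. With an estimated correlation the HSC signature and S phase lists passed the list test, while the lists of G2 and M phase (adjusted p = 0.0521), megakaryocyte and platelet (adjusted p = 0.0721) and erythroid genes (adjusted p = 0.115), higher with the preset correlation, did not. Procr, which encodes the endothelial protein C receptor used to enrich HSCs (chromosome 2, 155751117 to 155755471, GRCm38), fell by 2.76 on the log2 scale (SE 0.35, adjusted p = 0.000183, n = 3 per bin). Cdkn1c, the cyclin-dependent kinase inhibitor p57 (chromosome 7, 143458339 to 143461050), fell by 1.98 (SE 0.20, adjusted p = 2.31e-06). Cdk6, the G1 kinase (chromosome 5, 3341485 to 3531008), was 2.31 higher (SE 0.096, adjusted p = 1.25e-11). Gata1, the erythroid and megakaryocyte transcription factor (chromosome X, 7959260 to 7978071), was 5.03 higher (SE 0.37, adjusted p = 7.85e-07). Itga2b, the platelet integrin CD41 (chromosome 11, 102453297 to 102470122), was 3.21 higher (SE 0.21, adjusted p = 1.79e-07).

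In that comparison limma called 2596 genes higher in GFP1 and 2872 lower at an adjusted p under 0.05, of which 1060 and 1018 changed at least 2-fold. Of the 306 immunoglobulin genes tested, 186 were among the higher genes, which leaves 2410 others. The 10 genes with the largest rise under the rule for named genes were all immunoglobulin genes, from Ighv8-12 (log2 11.67, SE 1.06) to Ighg2c (15.54, SE 0.69). Their GFP4 means ran from 0.14, the lowest value of the file, to 4.59 (Ighv1-34 and Ighg2b), so the size of these folds depends on the offset in the authors' values. The 10 largest outside them, chosen after their values were seen, were Jchain (8.80, SE 1.81), Prg2 (6.52, SE 1.98), Slpi (5.62, SE 0.35), Derl3 (5.33, SE 0.51), Mzb1 (5.23, SE 0.36), Gata1, Mfsd2b (4.87, SE 0.26), Fgf3 (4.76, SE 0.50), Gp1bb (3.77, SE 0.37) and Tuba8 (3.69, SE 0.17). Jchain, Derl3 and Mzb1 are genes of antibody-secreting cells. Prg2 passed narrowly (adjusted p = 0.0419) and missed the threshold with the replicate block (adjusted p = 0.0607), with a pseudocount of 0.1 (adjusted p = 0.107) and without most single libraries. The 10 genes with the largest fall were Ski, Smtnl1, Khdrbs3, Plk2, Cyp26b1, Heca, Tns2, Cldn5, Gbp10 and Cnnm3. Some of them differed widely between the libraries of a middle bin. In GFP3 replicates I, II and III, Ski was 8.81, 9.13 and 11.90 and Khdrbs3 7.96, 7.07 and 10.29. In the GFP2 replicates, Heca was 7.22, 7.79 and 10.10 and Cnnm3 8.43, 8.38 and 11.35. In each case replicate III lay nearest to the GFP4 values, so the middle-bin means of these genes join unlike libraries. Ski, a repressor of TGF-beta signalling, fell by 3.86 (SE 0.65, adjusted p = 0.00147). Cyp26b1, which degrades retinoic acid, fell by 3.54 (SE 0.185, adjusted p = 3.52e-10), and Cnnm3 fell by 3.22 (SE 0.66, adjusted p = 0.0049). Because GFP1 held immunoglobulin transcripts, GFP2 was also set against GFP4 with the GFP1 and Total libraries left out, an alternative chosen after seeing the data; it called 785 genes higher in GFP2 and 569 lower.

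Of the 40 genes in the HSC signature, a list fixed beforehand, 32 were lower in GFP1 than in GFP4 and 1 was higher (34 and 1 adjusted over the list alone); the median log2 difference was −1.09. The list test, camera, gave an adjusted p of 5.89e-26, and 0.0108 with an estimated correlation. Sult1a1 (log2 −3.08, SE 0.11) and Hlf, an HSC transcription factor (−1.83, SE 0.088), had the smallest p. Fgd5 fell by 1.84 (SE 0.15, adjusted p = 8.16e-08), Mecom by 1.38 (SE 0.12, adjusted p = 5.87e-08) and Hoxb5 by 1.22 (SE 0.21, adjusted p = 0.000235). The HSC markers Vwf (0.079, SE 0.23, adjusted p = 0.895), Slamf1 (−0.29, SE 0.11, adjusted p = 0.0787) and Kit (−0.55, SE 0.24, adjusted p = 0.15) did not pass; Vwf changed sign without GFP4 replicate I (−0.049) or GFP1 replicate III (−0.14). Slamf1 and Kit lay near the threshold: both passed with array weights (adjusted p = 0.0193 and 0.045), Slamf1 also with the filter at 1 ppm (adjusted p = 0.0373) and without GFP4 replicate I or GFP1 replicate I, and Kit also without Total replicate III (adjusted p = 0.0156) and with the compared groups alone (adjusted p = 0.00801). Interferon response genes were lower as a group: 23 of 30 fell and none rose (26 lower adjusted over the list alone), with an adjusted p of 1.2e-18 by camera and 0.00353 with an estimated correlation. Among them were Ifi44 (−1.65, SE 0.098) and Oasl2 (−1.31, SE 0.087). Age-associated HSC genes had 10 lower and 3 higher of 22 (12 and 3 adjusted over the list alone; adjusted p = 0.00174, and 0.368 with an estimated correlation).

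**Figure D2:**
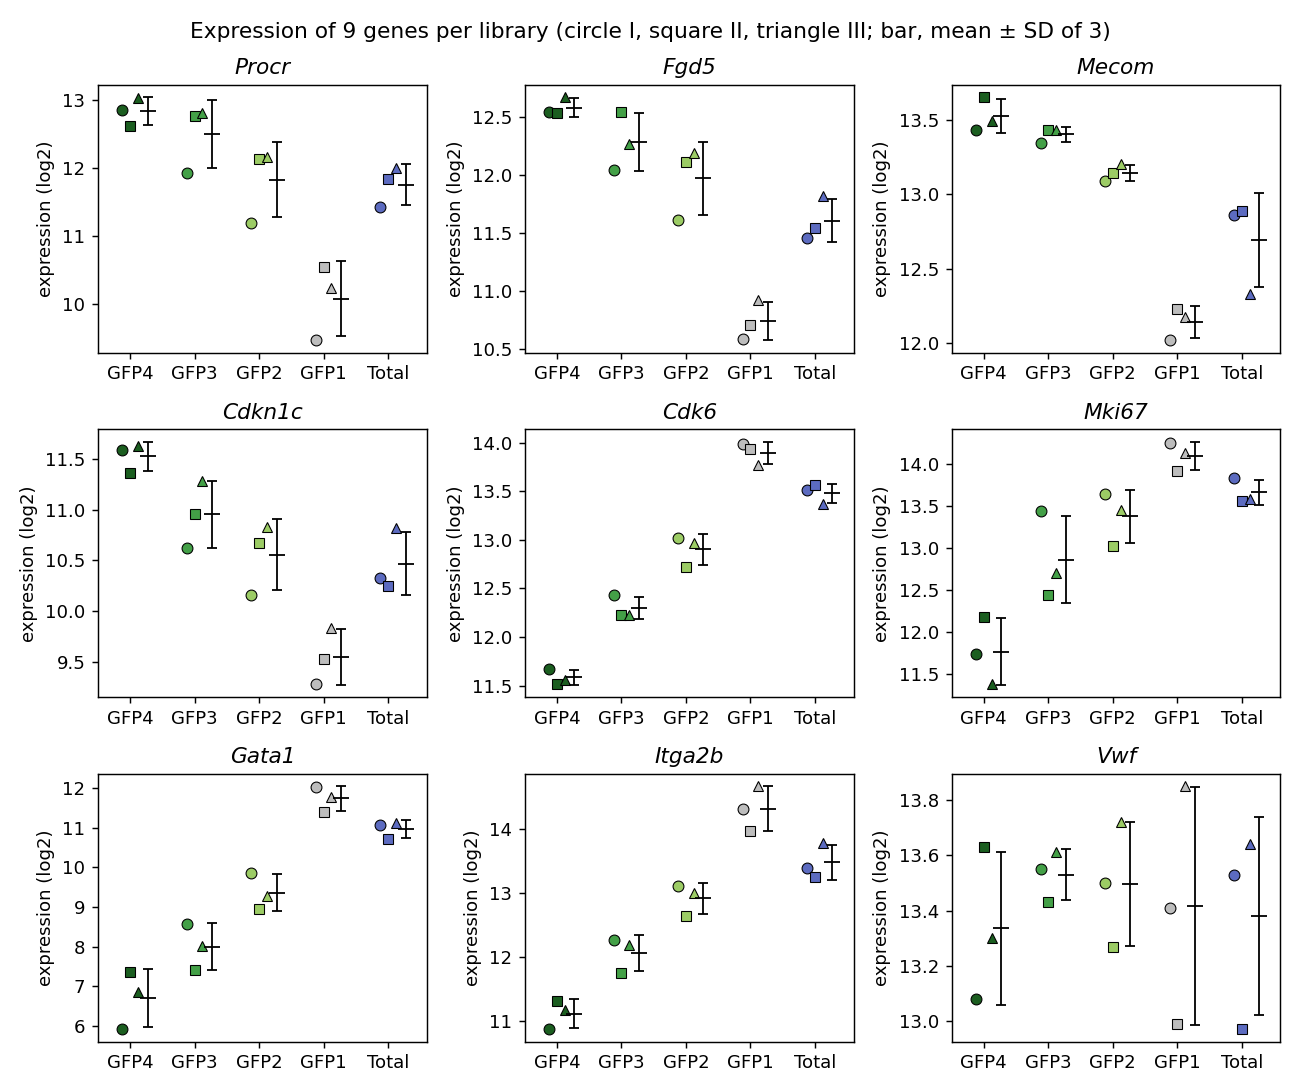
Log2 expression of 9 genes per library (points) in the 4 bins and Total, with mean ± SD of 3 libraries. Procr, Fgd5, Mecom and Cdkn1c have their highest mean in GFP4 and lowest in GFP1, Cdk6, Mki67, Gata1 and Itga2b the opposite, and Vwf means lie between 13.34 and 13.53.

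Cell cycle genes were higher in GFP1 almost without exception. Of 42 S phase genes 41 rose (41 adjusted over the list alone), with a median of 1.39 and an adjusted p of 2e-43 (0.0426 with an estimated correlation). Of 52 genes of G2 and M phase 51 rose (52 adjusted over the list alone), with a median of 2.08 and an adjusted p of 3.94e-51 (adjusted p = 0.0521 with an estimated correlation, which misses the threshold). Examples were Cdca7 (1.37, SE 0.087), Uhrf1 (1.86, SE 0.12), Cdca8 (2.34, SE 0.17) and Mki67, the proliferation marker (2.33, SE 0.27). G1 entry and quiescence regulators split, with 13 of 27 higher and 7 lower (13 and 8 adjusted over the list alone; adjusted p = 0.0345, and 0.172 with an estimated correlation): Cdkn2c rose by 2.34 (SE 0.21) while Ndn fell by 1.61 (SE 0.12). That list missed the threshold with the replicate block (adjusted p = 0.0583). Ribosome biogenesis genes rose in 26 of 30 cases (27 adjusted over the list alone; adjusted p = 7.13e-17, and 0.00353 with an estimated correlation), with Nhp2 at 1.09 (SE 0.12). Oxidative phosphorylation genes rose in 26 of 36 (32 adjusted over the list alone; adjusted p = 6.99e-16, and 0.115 with an estimated correlation), with Ndufa1 at 1.08 (SE 0.13). Glycolysis genes split, with 4 of 20 higher, among them Ldha (0.53, SE 0.091), and 7 lower, among them Ldhb (−1.33, SE 0.11); the list's adjusted p was 0.13, and 4 and 7 passed adjusted over the list alone.

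Among lineage genes, of 29 megakaryocyte and platelet genes 16 rose and 3 fell (16 and 5 adjusted over the list alone; adjusted p = 1.58e-07, and 0.0721 with an estimated correlation), among them Gp5 (2.86, SE 0.17) and F2rl2 (3.00, SE 0.19), while Mylk fell by 1.58 (SE 0.15). Of 25 erythroid genes 14 rose and 2 fell (15 and 3 adjusted over the list alone; adjusted p = 3.16e-06, and 0.115 with an estimated correlation), among them Epor, the erythropoietin receptor (2.34, SE 0.19). Of 25 granulocyte-monocyte genes 5 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0324, and 0.627 with an estimated correlation). Mpo (1.19, SE 0.59, adjusted p = 0.226) and Cebpa (0.33, SE 0.39, adjusted p = 0.694) did not pass, and Cebpa was −0.16 without GFP1 replicate II. Of 24 lymphoid genes 8 rose and 4 fell (8 and 4 adjusted over the list alone; adjusted p = 0.0208, and 0.314 with an estimated correlation), with the immunoglobulin gene Ighm rising most (5.88, SE 1.04), Mzb1 having the smallest p among those that rose, and Notch1 falling by 1.20 (SE 0.13). Multipotent progenitor markers had 3 higher and 4 lower of 12 (adjusted p = 0.617; 3 and 4 adjusted over the list alone). Cd34 rose by 0.94 (SE 0.095, adjusted p = 5.62e-07). Cd48, whose protein the sort excluded, was 2.02 higher in GFP1 (SE 0.54, adjusted p = 0.0208), a call lost without GFP4 replicate II (adjusted p = 0.0817), GFP4 replicate III (adjusted p = 0.0773) or GFP1 replicate II (adjusted p = 0.0754). In the same libraries, markers of other blood cells moved: 6 of 12 B cell markers were higher (6 adjusted over the list alone; adjusted p = 0.000214, and 0.306 with an estimated correlation), as were 5 of 14 T and NK cell markers with 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.0011, and 0.146 with an estimated correlation). The B cell list includes the immunoglobulin gene Iglc2, so its count partly restates the immunoglobulin result. In a quantile normalization without immunoglobulin genes, which drops Iglc2, the list's camera adjusted p was 0.013. None of 12 neutrophil or 12 macrophage markers passed, over all genes or adjusted over the list alone.

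Polycomb and chromatin genes moved in different directions. Of 11 tested subunits of Polycomb repressive complex 2 (PRC2), 6 rose and 2 fell (6 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.225). Ezh2, the methyltransferase of dividing cells (chromosome 6, 47530139 to 47595341), was 1.37 higher in GFP1 (SE 0.14, adjusted p = 8.93e-07), and its paralog Ezh1 (chromosome 11, 101191115 to 101226463) fell by 1.23 (SE 0.11, adjusted p = 7.61e-08). The core subunits Suz12 (0.49, SE 0.13, adjusted p = 0.00791) and Eed (0.38, SE 0.11, adjusted p = 0.0152) also rose, and missed the threshold without GFP1 replicate III (adjusted p = 0.0538 and 0.0629). Of 18 PRC1 subunits 2 rose and 7 fell (2 and 7 adjusted over the list alone; adjusted p = 0.0536), with Cbx7 falling by 1.30 (SE 0.11) and Cbx6 by 1.14 (SE 0.10). In the DNA methylation list 5 of 14 rose, with Dnmt1 at 1.32 (SE 0.11), and 1 fell (5 and 4 adjusted over the list alone); its median was −0.15 while camera gave the direction up (adjusted p = 0.3). H3K27 demethylase and trithorax genes had 2 higher and 3 lower of 14 (2 and 4 adjusted over the list alone; adjusted p = 0.7).

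**Figure D3:**
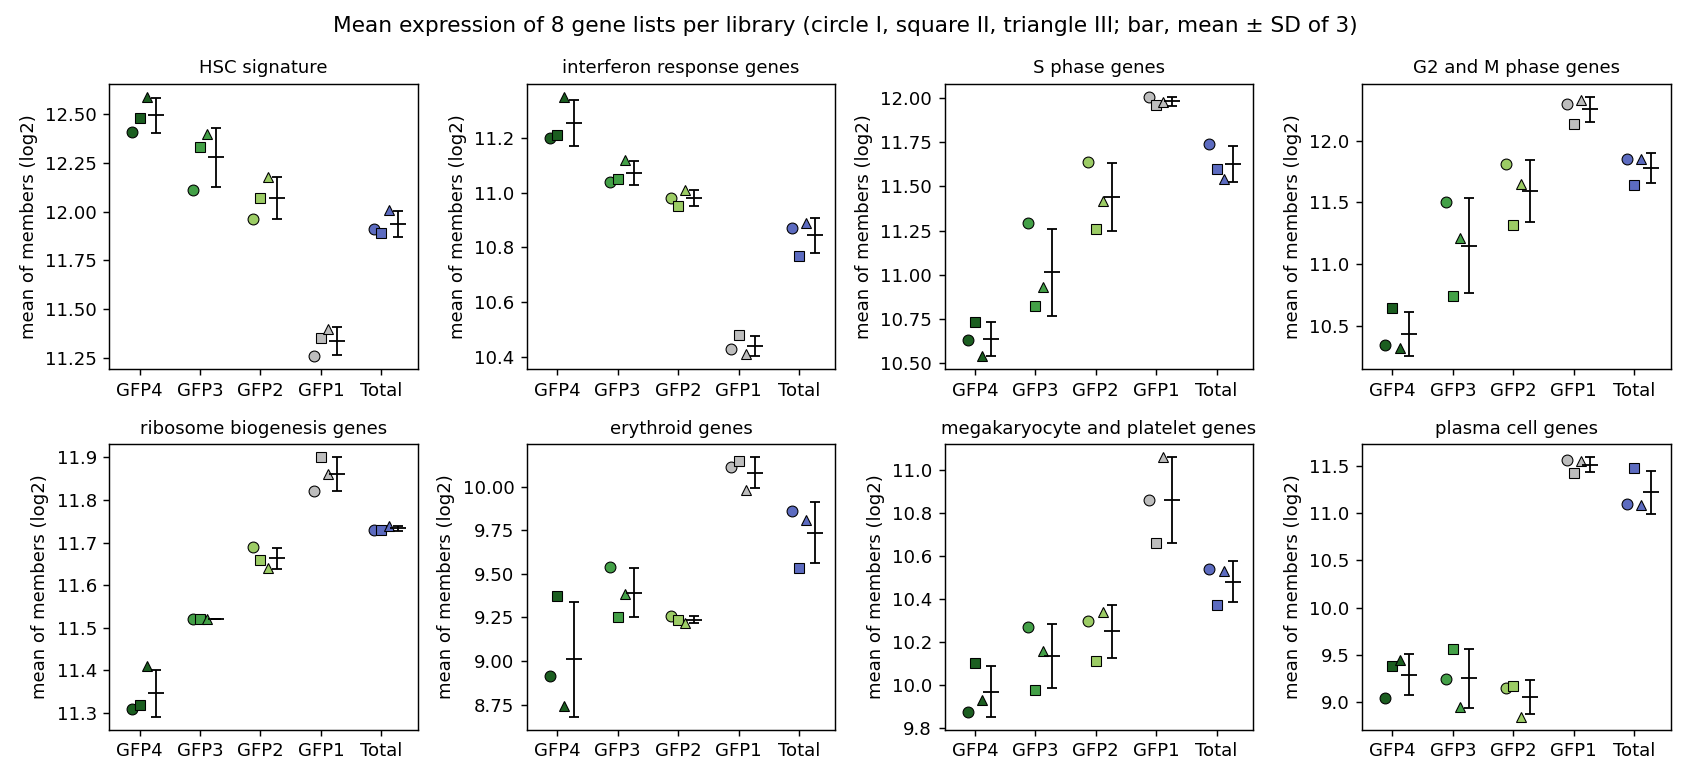
Mean log2 expression over the members of 8 gene lists per library (points), with mean ± SD of 3 libraries. The HSC signature falls from 12.49 in GFP4 to 11.33 in GFP1, the G2 and M phase list rises from 10.44 to 12.26, and the plasma cell list, chosen after seeing the data, lies at 9.06 to 9.29 in GFP4, GFP3 and GFP2 and at 11.51 in GFP1.

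The trend over the 4 bins asked whether expression was graded. It was tested as a log2 change per step from GFP4 towards GFP1, and limma called 2687 genes rising and 2931 falling. By smallest p the rising genes were Ighv3-6, Cdk6 (0.75 per step, SE 0.031), Tuba8 (1.22, SE 0.055), Slc22a3, an organic cation transporter (1.07, SE 0.051), and Emid1 (0.71, SE 0.039). The falling genes were Sult1a1 (−0.99, SE 0.036), Hlf (−0.58, SE 0.028), Cyp26b1 (−1.14, SE 0.059), Nceh1 (−0.52, SE 0.027) and Tinagl1 (−0.73, SE 0.039). Mean Cdk6 values were 11.58 in GFP4, 12.30 in GFP3, 12.91 in GFP2 and 13.90 in GFP1. Of the genes higher in GFP1 than in GFP4, 76.3% had GFP2 and GFP3 means in bin order between them, and of the lower genes 77.1%. These genes were chosen because the ends differ, which by itself favours that order, and no chance value was computed for such a set. GFP2 against GFP3 shares no library with GFP1 against GFP4. There, 88.1% of the genes higher and 88.4% of the genes lower in GFP1 had the same sign, against 56.3% of the genes not called.

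The 3 steps between neighbouring bins were unequal in the genes they called. From GFP4 to GFP3, 12 genes were higher and 4 lower. Under the rule for named genes these were Slc22a3 (1.27, SE 0.16), Tuba8 (1.02, SE 0.17) and Cit, the citron kinase of cytokinesis (0.95, SE 0.17), and on the lower side Igf2bp2 (−1.54, SE 0.23), Ahnak (−1.29, SE 0.19) and Cyp26b1 (−1.08, SE 0.19). Over all genes, 0 of 52 genes of G2 and M phase and 1 of 42 S phase genes were higher in GFP3 than in GFP4 (45 and 21 adjusted over the list alone), and camera called both lists higher (adjusted p = 1.72e-59 and 4.36e-30), but not with an estimated correlation (adjusted p = 0.0562 and 0.0947). In the same step camera called the 12 macrophage markers higher (median 0.98, adjusted p = 3.67e-05) and the 12 endothelial and stromal markers lower (median −0.40, adjusted p = 0.0375), with 0 members past the threshold; with an estimated correlation the adjusted p was 0.429 for each. Each of the 6 named calls was lost without GFP4 replicate III, and all but that of Slc22a3 also without GFP4 replicate I or GFP3 replicate I. Ahnak, Tuba8 and Cit were lost with the compared groups alone (adjusted p = 0.0979, 0.136 and 0.113), and Tuba8, Cit and Cyp26b1 with no filter (adjusted p = 0.052, 0.0614 and 0.052) and with the covariate of genes at the lowest value (adjusted p = 0.0641, 0.0803 and 0.0641). This count of 16 became 48 with the replicate block, 122 without GFP3 replicate II, 5 without GFP4 replicate I, GFP1 replicate I or GFP1 replicate II, 6 without GFP1 replicate III, 7 without GFP2 replicate III, 1 without GFP3 replicate I and 0 without GFP4 replicate III. From GFP3 to GFP2, limma called 0 genes, with 1569 at an unadjusted p under 0.05, and 5 genes with the replicate block. No S phase gene and no gene of G2 and M phase passed over all genes (34 of 42 and 1 of 52 adjusted over the list alone), and camera called both lists higher (adjusted p = 8.85e-40 and 2.13e-28), but not with an estimated correlation (adjusted p = 0.108 and 0.222). Camera called the 12 neutrophil markers lower in GFP2 than in GFP3 (median −0.53, adjusted p = 0.0293, and 0.785 with an estimated correlation), with 0 members past the threshold. Leaving out GFP3 replicate I gave 19 genes, GFP2 replicate III 8, GFP2 replicate II 4 and Total replicate III 3.

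From GFP2 to GFP1, 858 genes were higher and 1149 lower, and this step brought in the immunoglobulin genes. Of these, 164 were higher, led by Igha (13.68, SE 3.01), Ighv8-8 (13.13, SE 0.78) and Igkv9-120 (12.28, SE 1.00), which leaves 694 others. The genes with the largest fall were Smtnl1 (−1.97, SE 0.50), Plk2, a kinase and p53 target (−1.94, SE 0.32), and Sult1a1 (−1.93, SE 0.11). Cell cycle lists rose in this step too (mean ± SD, n = 3). The S phase list went from 11.44 ± 0.19 in GFP2 to 11.98 ± 0.025 in GFP1, and the G2 and M phase list from 11.59 ± 0.25 to 12.26 ± 0.10. The HSC signature had 28 of 40 members lower and none higher (32 lower adjusted over the list alone; adjusted p = 6.04e-28, and 0.0122 with an estimated correlation), with a median of −0.69. Megakaryocyte and platelet genes had 11 of 29 higher and 1 lower (14 and 3 adjusted over the list alone; adjusted p = 8.11e-09), and erythroid genes 10 of 25 higher and 1 lower (15 and 2 adjusted over the list alone; adjusted p = 1.82e-09); with an estimated correlation both had an adjusted p of 0.0464. Beside these, 7 of 12 B cell markers were higher (7 adjusted over the list alone; adjusted p = 1.82e-09, and 0.103 with an estimated correlation), as were 7 of 14 T and NK cell markers with 1 lower (9 and 1 adjusted over the list alone; adjusted p = 2.08e-07, and 0.0464 with an estimated correlation). The B cell list includes the immunoglobulin gene Iglc2, so it is not independent of the immunoglobulin result. Lists of other cell types also differed in mean, in both directions (mean ± SD, n = 3). Macrophage markers were 10.80 ± 1.28 in GFP2 and 9.61 ± 1.72 in GFP1. Neutrophil markers were 11.84 ± 0.60 and 12.29 ± 0.36, and mast cell and basophil markers 5.01 ± 0.48 and 6.05 ± 0.68. The calls of Igha and Smtnl1 were lost without several single libraries, and that of Smtnl1 also in a quantile normalization without immunoglobulin genes (limma adjusted p = 0.0547). The count of 2007 became 1217 without GFP2 replicate II, 1203 without GFP2 replicate III, 1282 without GFP1 replicate I and 1229 without GFP1 replicate III.

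Each bin was set against Total, which shows where the undivided sort lies among its parts. GFP4 differed most, with 1317 genes higher and 1482 lower. GFP3 had 188 and 411, GFP1 89 and 395, and GFP2 3 and 89; the order of GFP3 and GFP1 turned with the number of genes at the lowest value as a covariate (296 and 435 genes). GFP3 against Total gave 927 genes with the replicate block, and GFP2 against Total 49 in a quantile normalization without immunoglobulin genes. These comparisons share the Total libraries. GFP4 was higher than Total for Khdrbs3 (3.58, SE 0.76), Ski (3.35, SE 0.65) and Heca (3.27, SE 0.62), and GFP3 for Rxra, the retinoid X receptor (1.77, SE 0.32), Phlpp1 (1.77, SE 0.39) and Tanc2 (1.52, SE 0.27). The call of Phlpp1 was lost with array weights (adjusted p = 0.0592), with that covariate (adjusted p = 0.0949) and without several single libraries, and the call of Rxra without GFP3 replicate II (adjusted p = 0.0517) or GFP3 replicate III (adjusted p = 0.0536). GFP1 was lower than Total for Plk2 (−1.94, SE 0.32), Cldn5 (−1.84, SE 0.33) and Tns2 (−1.82, SE 0.25), and higher for the immunoglobulin segments Ighv5-16 (7.83, SE 0.81), Igkv6-20 (7.39, SE 1.20) and Igkv1-99 (5.99, SE 1.09). Calls were lost for Plk2 without GFP1 replicate I (adjusted p = 0.0519), for Cldn5 and Igkv1-99 with the compared groups alone (adjusted p = 0.0532 and 0.44), for Igkv1-99 also without GFP1 replicate III (adjusted p = 0.0523), and for Igkv6-20 with a pseudocount of 0.1 (adjusted p = 0.0703). The 3 largest falls against Total were immunoglobulin genes in GFP2 (Ighv1-9, whose call was lost with array weights, with a pseudocount of 0.1 and without most single libraries, Ighv8-8, and Ighg2b, whose call was lost with the compared groups alone), GFP3 (Ighg2c, Ighg2b and Ighv3-6) and GFP4 (Ighg2c, Ighv3-6 and Ighv8-8). The 3 genes higher in GFP2 than in Total were mt-Co1 (0.72, SE 0.073), Eef1a1 (0.48, SE 0.094) and Ubb (0.38, SE 0.069). By limma, Eef1a1 lost its call with the replicate block (adjusted p = 0.0565) and with no filter (adjusted p = 0.0522). Ubb lost its call with the compared groups alone (adjusted p = 0.0695), and both lost it without several single libraries. None of the 3 genes passed when the quantile normalization was repeated without immunoglobulin genes, an alternative chosen after seeing the data: mt-Co1 was then 0.060, Eef1a1 0 and Ubb −0.021. Counts moved by over 1.5 times without GFP1 replicate I (276) or GFP1 replicate III (198) for GFP1, without GFP2 replicate III (57) for GFP2, and without GFP3 replicate II (201) or GFP3 replicate III (240) for GFP3. Fitted to the compared groups alone, the totals were 1660 for GFP4, 144 for GFP3, 50 for GFP2 and 89 for GFP1.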

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

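The tests in this part that were chosen only after the result was seen are those on mature B cells, on dilution of stem cell genes and on the graded change; the tests on plasma cells, misassigned reads and rank shifts were set before their values were seen. The test of dilution as the whole cause replaced an earlier one, with the same outcome, that took Slamf1 as its reference, and the spread was added to the mitochondrial test after its value was seen.

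The step from GFP2 to GFP1 differed from the step from GFP3 to GFP2 for 42 genes by a limma interaction test, 36 with a positive and 6 with a negative difference between the steps; 19 of the 36 were immunoglobulin genes. The slope along the bins differed between replicates II and I for 6 genes, all steeper upwards in replicate II: AW822252, Cox7c, Gm10094, Gm29013, Hist1h2ao and Tmsb10. Between replicates III and I limma called 0 genes, with 1360 at an unadjusted p under 0.05. The replicates differ in age and length of doxycycline, with 1 library per bin each, so this comparison has no replicates of its own.

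Immunoglobulin transcripts were abundant in the GFP1 and Total libraries and took at most 0.0737% of the summed linear values elsewhere. Reads of other genes assigned to immunoglobulin segments are argued against, because 19 of 22 plasma cell genes that are not immunoglobulins were higher in GFP1 than in GFP2. Plasma cells in the GFP1 and Total sorts, or RNA from them, are a candidate source: the median log2 difference of those 22 genes was 1.40, with Jchain, the most abundant in GFP1, at a mean of 17.09 against 5.34, although 11 of the 22 also reach a mean of 10 in GFP2, GFP3 or GFP4 and 1 is in another list, and the lineage depletion and the c-Kit gate should remove such cells. For mature B cells the median over 9 genes was 0.68, between the bounds set for and against, so B cells stay open. Whether cells without the label fall into GFP1 by definition of the bins cannot be tested here, and a biological difference between HSCs of the bins was not tested for these genes.

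Stem cell genes were lower in GFP1 than in GFP2, with an HSC signature median of −0.69. Marker lists of other cell types differed between the same bins as well. From GFP2 to GFP1 the list mean went from 10.80 to 9.61 for macrophage, 11.84 to 12.29 for neutrophil, and 5.01 to 6.05 for mast cell and basophil markers. Dilution by RNA of other cells as the whole cause was tested on the premise that it lowers all members alike. Of the 40 members, 47.5% lay more than 2 SE from the common fall of −0.68, 10 further below it and 9 above it. Members that the other cells also express would fall less, and quantile normalization shifts genes by rank, so this spread cannot decide. A second test of dilution did not decide either. Slamf1 (−0.16, SE 0.11) and Vwf (−0.078, SE 0.23) lay above the signature's median by more than the bound of 0.5 set for each. Kit (−0.46, SE 0.24) lay above that median by 0.23. The sort selected every bin for CD150 and c-Kit, the proteins of Slamf1 and Kit. Other cells in the GFP1 sort would have passed the same gate, so these genes cannot count against dilution. Vwf alone, with an SE of 0.23, cannot decide. Dilution therefore stays open for all or part of the fall. A graded change along the bins predicts a fall before GFP1 too. The signature's list means were 12.49 in GFP4, 12.28 in GFP3, 12.07 in GFP2 and 11.33 in GFP1, so the last step was the largest. A fall at the earlier steps cannot tell the cause of that last step. In GFP2 against GFP4, where immunoglobulin transcripts took at most 0.0737% of the summed values, the signature's median was −0.44 (19 of 40 lower, none higher). Camera gave an adjusted p of 6e-16 with the preset correlation, which met the prediction, and 0.146 with an estimated correlation, which did not. That comparison is not free of other cell types' markers: camera called macrophage markers higher (median 1.39, adjusted p = 8.99e-06) and neutrophil (adjusted p = 0.0163) and endothelial and stromal markers (adjusted p = 0.0122) lower, none of them with an estimated correlation (adjusted p = 0.425, 0.74 and 0.221). In replicates I, II and III the macrophage list mean was 10.16, 8.66 and 9.22 in GFP4 and 9.64, 12.18 and 10.57 in GFP2. The bins thus overlapped, and replicate I showed no rise.

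Mitochondrially encoded transcripts were lower in GFP1 than in GFP2, with a median of −0.50 and 6 of 13 genes past the threshold. Immunoglobulin genes at the top ranks push other abundant genes down in a quantile normalization, and when it was repeated without them the median was −0.253 (SE 0.087) and 1 of 13 passed. That lies at the bound of −0.25 set against this explanation and within its spread, so the rank shift may account for part of the difference, and whether it accounts for all of it cannot be told apart from a lower mitochondrial content with these libraries. For ribosomal protein genes, 27 of 84 were lower in GFP1 than in GFP2 as deposited and 13 after that normalization.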

How the results depend on the processing

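Settings added after seeing the data are the filter at 1 ppm, median-of-ratios rescaling, the covariate of genes at the lowest value, quantile normalization without immunoglobulin genes and the fits without GFP1 and Total. Fitted to the GFP4 to GFP2 libraries alone, 785 genes were higher and 569 lower in GFP2. Over these 3 bins the trend is the same contrast at another scale, so it gives the same counts by construction. For GFP1 against GFP4 and the trend, counts stayed within 1.5 times under every other setting. Without single libraries, GFP1 against GFP4 gave 2072 to 2844 higher and 2329 to 3204 lower genes. GFP3 against GFP4 (16 genes) gave 7 with no filter, 48 with the replicate block, 10 with the filter at 1 ppm, 5 with the covariate, 10 with the 2 groups alone and 0 to 122 without single libraries. GFP2 against GFP3 (0 genes) gave 2 with array weights, 5 with the replicate block, 1 without immunoglobulin genes and 0 to 19 without single libraries. Single libraries left out gave 1203 to 2489 genes for GFP1 against GFP2, and against Total 198 to 564 for GFP1, 57 to 124 for GFP2 and 201 to 628 for GFP3. With the compared groups alone, 89 genes differed from Total in GFP1, 50 in GFP2, 144 in GFP3 and 1660 in GFP4; fewer libraries then estimate the spread. GFP2 against Total gave 49 without immunoglobulin genes, and GFP3 against Total 927 with the replicate block and 296 with the covariate. Lists past the threshold in GFP1 against GFP4 fell from 11 higher and 5 lower to 2 and 2 with an estimated correlation, and to 7 higher in GFP2 against GFP4; the trend's 9 and 5 became 2 and 2. With fry, GFP1 against GFP4 gave 12 higher and 7 lower lists. Fry, unlike preset camera, called PRC1 (adjusted p = 6.12e-05), glycolysis (0.000601) and p53 target genes (0.00228) lower. It also called the DNA methylation (0.000105) and mast cell and basophil lists (0.0172) higher. It did not call the granulocyte-monocyte (0.195) or ribosomal protein list (0.28). The G2 and M phase (8.86e-06) and erythroid lists (0.000226) passed by fry. Where no construction shows it, the cause was not tested. Of 207 named gene results 43 changed in at least 1 setting. Without a change of sign, 38 lost their call, in 177 results of a gene in a setting, and 2 gained one (Slamf1 and Kit). A change of sign occurred for 4. Without immunoglobulin genes these were Ubb in GFP2 against Total (−0.021, limma adjusted p = 0.986) and mt-Co1 in GFP1 against GFP4 (0.073, adjusted p = 0.651). Both also lost their calls there. Without single libraries they were Vwf (−0.14 to 0.29) and Cebpa (−0.16 to 0.90), neither past the threshold. Replicate numbers share an age and a length of doxycycline but no stated animal or day: same-numbered libraries' deviations correlated from −0.41 to 0.59, 21 of 30 pairs above 0.1, and 13 of 15 libraries correlated best with their own number, a hint from the data. With this block GFP1 against GFP4 gave 2787 higher and 3139 lower genes, sharing 5443 calls with the 5468 above. Size factors and tests for counts, and tests per transcript, were not run because the values are log2 per gene. Of 10 splits of the 6 libraries in each comparison of 3 against 3, too few for a share under 0.05, 1 gave as many genes as the real one, except GFP2 against GFP3, where all 10 did (0 genes, highest other 1). Real and highest other counts were 5468 and 0 for GFP1 against GFP4, 16 and 0 for GFP3 against GFP4, 2007 and 0 for GFP1 against GFP2, and against Total 484 and 5 (GFP1), 92 and 56 (GFP2), 599 and 2 (GFP3) and 2799 and 1 (GFP4). Each other split mixed libraries of the compared groups, so any difference between them entered the spread. Low counts in those splits were thus favoured in advance and cannot weigh against chance. For the trend, 1 of 100 splits of the 12 bin libraries gave 5618, the real one, which is the smallest share these splits could give. The splits ignored replicate number. The highest other split gave 4026, so a high count does not need the bin order and is no test of a graded change. Depth is unknown, so its limits could not be given.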

Other observations

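Further gene groups were compared between GFP1 and GFP4. Of 20 p53 target genes 3 were higher and 5 lower (3 and 7 adjusted over the list alone; camera adjusted p = 0.206), with Psrc1 at 1.98 (SE 0.27) and Plk2, also among the largest falls, at −3.58 (SE 0.32). Of 21 immediate early genes 2 were higher and 5 lower (3 and 5 adjusted over the list alone; adjusted p = 0.225): Btg2 rose by 1.36 (SE 0.17) and Klf6 fell by 1.03 (SE 0.14). Of 18 cholesterol synthesis genes 1 was higher, Fdps (0.59, SE 0.11), and 4 lower (1 and 4 adjusted over the list alone; adjusted p = 0.701). Of 6 sort gate markers 2 were higher and 2 lower (2 and 4 adjusted over the list alone; adjusted p = 0.7), with a median of −0.42 and a mean of 0.09. Of 9 mast cell and basophil markers 1 was higher, Cpa3 (2.60, SE 0.42), and 1 lower, Il4, a call lost in 3 settings (4 and 1 adjusted over the list alone; adjusted p = 0.0931). Of 12 endothelial and stromal markers 2 were lower, Emcn (−1.44, SE 0.16) and Kdr, a call lost in 3 settings (2 adjusted over the list alone; adjusted p = 0.225). Of 84 ribosomal protein genes 2 were higher and 14 lower (2 and 15 adjusted over the list alone; adjusted p = 0.00989, 0.769 with an estimated correlation, and 0.103 in a quantile normalization without immunoglobulin genes). Of 13 mitochondrially encoded genes 7 were lower (7 adjusted over the list alone, camera adjusted p = 8.88e-06, and 0.232 with an estimated correlation). In a quantile normalization without immunoglobulin genes the list's camera adjusted p was 0.0304. There, by limma, mt-Co1 (0.073, adjusted p = 0.651) and mt-Co2 (−0.15, adjusted p = 0.329) lost their calls.

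The lists added after seeing the data gave, in GFP1 against GFP4, 21 of 22 plasma cell genes higher, 186 of 306 immunoglobulin genes higher, 7 of 12 late megakaryocyte and platelet genes higher with a median of 1.17, and 5 of 12 late erythroid genes higher with a median of 0.47. Of 10 early erythroid and megakaryocyte regulators 3 were higher, among them Gata1 and Epor, and 4 lower (3 and 4 adjusted over the list alone), with a median of −0.044, a mean of 0.604 and a camera adjusted p of 0.783, so that list did not move as a group. Differentiated erythroid cells and megakaryocytes or platelets in the GFP1 sort were drafted as explanations for those regulators, with bounds of 1 for and 0.5 against on the median of each late list; they were left out after these values were seen, because the regulators had not moved together, and are given here as values only. No spread of these medians was computed, so neither bound decides. A graded change of the regulators was drafted and left out in the same way; their median in GFP2 against GFP4 was −0.057.

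Without the libraries that held most immunoglobulin transcripts, some lists kept their direction and others did not. In GFP2 against GFP4, 39 of 52 genes of G2 and M phase and 34 of 42 S phase genes were higher, 13 of 30 ribosome biogenesis genes were higher, and 11 of 30 interferon response genes were lower with 1 higher; with an estimated correlation the adjusted p was 0.146 for the S phase, G2 and M phase and interferon lists and 0.0391 for ribosome biogenesis. The erythroid list did not pass (3 of 25 higher and 2 lower, adjusted p = 0.244), nor did the age-associated list (adjusted p = 0.821). The lymphoid list turned down (0 of 24 higher and 2 lower, adjusted p = 0.0378, and 0.575 with an estimated correlation) and ribosomal protein genes turned up (6 of 84 higher, adjusted p = 7.2e-12, and 0.495 with an estimated correlation). Markers of other cell types moved by camera although 0 macrophage or neutrophil genes and 1 of 12 endothelial and stromal genes passed: macrophage markers up (median 1.39, adjusted p = 8.99e-06), neutrophil markers down (median −0.61, adjusted p = 0.0163) and endothelial and stromal markers down (median −0.50, adjusted p = 0.0122). With an estimated correlation their adjusted p was 0.425, 0.74 and 0.221. The macrophage list means of single libraries overlapped between GFP4 and GFP2, with no rise in replicate I. By limma, Gata1 was 2.66 higher (SE 0.40, adjusted p = 0.0037), Cdk6 1.32 higher (SE 0.095, adjusted p = 5.85e-06) and Sult1a1 −1.15 (SE 0.099, adjusted p = 2.91e-05). Itga2b (1.81, adjusted p = 0.000505), Mecom (−0.38, adjusted p = 0.00648) and Cdkn1c (−0.98, adjusted p = 0.0163) also passed. Other genes named for GFP1 against GFP4 did not: Procr (−1.01, SE 0.35, adjusted p = 0.229), Fgd5 (−0.61, SE 0.16, adjusted p = 0.0564), Hoxb5 (−0.16, SE 0.21, adjusted p = 0.832) and Mki67 (1.61, SE 0.33, adjusted p = 0.0507). Of the genes higher in GFP1 than in GFP4, 742 were also called higher in GFP2 than in GFP4 and 0 lower, and of the lower genes 545 and 0; independent lists would share 72.8 and 58.4. Both comparisons share the GFP4 libraries: over 10337 genes their fold changes correlated at r = 0.547 against 0.501 in simulated unchanged groups, with covariances of 0.257 and 0.0404, and part of the overlap may come from the shared libraries; the comparison that shares none, GFP2 against GFP3, gave the 88.1% and 88.4% above.

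On the first principal component the Total libraries lay between GFP1 and the other bins, at 35.5, 49.9 and 42.0, with the GFP1 libraries at 66.5 to 70.5 and the GFP2 libraries at −36.9 to −23.8. On the second, with 8.23% of the variance, Total replicates I (−36.0) and III (37.9) lay outside all other libraries (−21.4 to 12.7). The immunoglobulin share of Total replicate II (5.49%) was above that of every GFP1 library (at most 5.28%). Such shares follow ranks in the common distribution, so they do not order the libraries by immunoglobulin RNA. Against all 4 bins at once, 2 genes were higher in Total, Gm16589 and Ighv1-11, and 0 were lower. Immunoglobulin segments above a log2 value of 8 numbered 60 to 83 in Total and 116 to 133 in GFP1.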
